A study of Homo sapiens with 274 samples.

How the data were processed

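The material was poly(A)-selected RNA from WM989-A6-G3-Cas9 5a3 cells, a clone of the established BRAF-mutant melanoma line WM989 that carries the Cas9 nuclease. Per the labels' protocols, mRNA was isolated with magnetic poly(A) beads, made into libraries with the NEBNext Ultra kit and sequenced as paired reads of 36 bases on a NextSeq 500. Each knockout library came from cells given 1 guide RNA, and the titles name the targeted gene and the guide. Controls were cells given guides without a target, named neg, and cells without a guide, named WT.

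The deposited table holds raw counts per gene for 274 libraries and 63677 genes. Per the submitters' processing notes, the authors aligned reads to the human genome build hg19 with STAR and counted them per gene with HTSeq to make these counts. Tool versions, the gene annotation release, the strand setting and the filters are not stated. The name of the table speaks of several sequencing runs, and it is not stated whether the runs of a library were summed. The values were whole numbers, with no scaling, and library totals differed. Mitochondrially encoded genes were listed and had 0 counts in every library, so no mitochondrial share could be used as a sign of RNA quality. A total of 31 symbols in the table are bare numbers, and genes were therefore followed by their Ensembl identifiers.

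Of the 274 libraries, 13 had no value for any gene, and 4 had between 316 and 4286 counts. These were left out by a minimum of 200000 counts, which left 257 libraries, of which 228 were knockout guides, 10 were neg and 19 were WT. Of 84 targets in the labels, 82 kept at least 1 library, and FGFR1 and POLR2A kept none. Totals per library ran from 381461 to 9304870 counts, with a median of 3331023, and 38 libraries had under 2000000. At these depths a gene at 1 CPM gives a few counts per library. The 50 most abundant genes took between 9.96% and 15.1% of a library's counts.

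Replicates of a target are its guides, and the labels do not say whether libraries are separate cultures, so the p-values rest on the spread between these libraries. For each gene that spread was pooled over all groups in a fit. A p-value or standard error therefore does not reflect how far a target's own guides disagree. ZFX mRNA in its own knockout, for instance, had 78.7 ± 39.7 CPM in 3 guides and a standard error of 0.10. All groups were fitted together in edgeR 4.0.16, run in R 4.3.3. Genes with low counts were removed by filterByExpr, which left 16635 genes, and libraries were scaled by TMM. Quasi-likelihood models with a trended dispersion were fitted, and each target was tested against neg by the quasi-likelihood F test, which is a test in either direction. Standard errors of log2 fold changes were the fold change divided by the square root of F. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. Targets with 1 guide got values and no count of calls. Values in CPM are means over libraries with the standard deviation, and other errors given after a ± sign are standard errors of a log2 fold change.

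A full account is given for 8 knockouts. SOX10, MITF, DOT1L, LATS2 and CSK were fixed by name, and the other 3 followed from a rule, as the further targets with at least 3 guides and the most called genes. In each of them the named genes were the targeted gene, the markers NGFR, EGFR, AXL, MITF and SOX10, and the 8 highest and 8 lowest log2 fold changes among called genes. Those genes needed a mean of at least 5 CPM in neg or in the target, a gene symbol that is no clone, antisense or pseudogene name, and the same sign in every guide. In addition, up to 4 called members of each called list were named. These choices, the lists and the tests were fixed before the data were examined.

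The lists held markers of melanocyte differentiation, neural crest, drug resistance, MAPK output, YAP-TAZ targets, p53 targets, interferon response, mitosis, DNA replication, cholesterol synthesis, the integrated stress response, the unfolded protein response, NF-kB targets, immediate early and AP-1 genes, SRF and cytoskeleton, extracellular matrix, hypoxia and glycolysis, the cytosolic ribosome, HOX genes, mitochondrially encoded genes, replication-dependent histones, fibroblast markers, keratinocyte markers and immune cell markers. They were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over all lists and targets. The correlation was also estimated for each list, and fry was run as an alternative. Of the 24 lists, the mitochondrially encoded list had 0 tested members.

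Markers and targeted genes were also adjusted over the targets for each gene. Likeness of guides was the Pearson correlation across genes of log2 deviations from the mean of neg, with guides permuted over targets 10000 times. Likeness of 2 knockouts was the correlation across genes of their log2 fold changes, each against a separate part of the neg libraries, so that chance values of shared controls did not add to it. Genes are not independent replicates in these correlations. Background came from groups of 3 WT libraries treated as if they were a target.

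Alternatives were RLE scaling, no filter on low counts, neg and WT together or WT alone as control, a minimum of 2000000 counts per library, the library number in blocks of 96 as a covariate, a 1.5-fold threshold with glmTreat, adjustment over all targets together, leaving out guides, fits of 1 target and neg alone, and DESeq2 1.42.0. The labels give no run or batch, so the library number in the titles stood in for it. The fit with that covariate reused the dispersion trend of the fit without it. Leaving out libraries under 1000000 counts, leaving out libraries at the far end of the first principal component, and DESeq2 on WT were added after the data had been seen. Guides were left out by number, from all targets in the same fit. A value for 1 target without a guide thus also reflects a changed shared fit. Where a choice left 1 guide, that library was assumed to vary like the other groups. The tests were tried on simulated counts before use. With 67 genes changed 2-fold, 89.6% were found with the libraries of SOX10 and 98.5% with those of LATS2. At 1.5-fold, 50.7% were found with the libraries of SOX10, 49.3% with those of LATS2 and 47.8% with those of CSK. The simulated counts held no block effect and no difference between guides beyond the fitted spread. Only genes of at least 5 CPM were changed, so these shares do not cover weaker genes such as NGFR and may be too high for the real libraries. Tables were read with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.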

Results

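Bulk RNA of human melanoma cells was profiled after knockout of 1 gene at a time. The cells were WM989-A6-G3-Cas9 5a3, a Cas9-carrying clone of the WM989 melanoma line, which bears an activating BRAF mutation. The targets came from genetic screens for cells with high NGFR and EGFR protein, a state that precedes drug resistance, and for cells that survive the BRAF inhibitor vemurafenib. Screen hits and genes that were no hits are both among them. After quality limits, knockout libraries covered 82 targets, of which 2 had 1 guide, 19 had 2, 58 had 3, 1 had 4 and 2 had 5. Controls were 10 neg libraries, from guides without a target, with 2594400 to 7761246 counts, and 19 WT libraries with 1082042 to 5601421 counts. Knockout libraries had 381461 to 9304870 counts.

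The targeted gene's own mRNA was compared with neg first. It fell in 39 of 80 tested targets, rose in 13 and was not called in 28, adjusted over the targets with edgeR. Of the 13, FEZF2, MAFA and FOXC2 were the 3 with under 5 CPM in neg, and their counts cannot be told apart from reads of the guide construct. NFATC2, a calcium-dependent transcription factor, fell with a log2 fold change of -1.55 ± 0.21, from 121 ± 14.6 CPM in 10 neg libraries to 41.6 ± 3.66 CPM in 3 guides. PTK2, the focal adhesion kinase, fell with -1.32 ± 0.10 (3 guides). GATA4, RELB and DEAF1 were the other genes that fell over 2-fold, with -1.13 ± 0.12, -1.08 ± 0.21 and -1.07 ± 0.14. Every guide lay below the neg mean in 35 of the 39. JUN, a subunit of the AP-1 transcription factor, rose with 1.44 ± 0.27 after its own targeting, and MITF rose with 1.10 ± 0.09. The median over the 72 targeted genes with at least 5 CPM in neg was -0.34. Cas9 leaves small insertions and deletions that need not lower an mRNA, so this comparison does not tell edited from unedited cells.

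Among the 80 targets with at least 2 guides, the number of called genes ran from 0 to 8357 of 16635, with a median of 65.5. SRF, a transcription factor of cytoskeletal and immediate early genes, had 8357 called genes, 4239 higher and 4118 lower. MITF and NFYA followed with 6698 and 6618. The splicing kinase PRPF4B had 6232, the chromatin remodeler INO80 5804, the spindle checkpoint kinase BUB1B 5437 and SOX10 5337. At least 100 genes were called in 34 targets. Between 1 and 99 genes were called in 29 targets, and 0 in the other 17. At unadjusted p under 0.05, edgeR gave 1328 genes in the SIX5 knockout. The rest of these 17 had at most 577, in the ZFP57 knockout. Such genes also arise by chance, so these numbers alone are no sign of a change. No other tool was run on these 17. As background, 48 groups of 3 WT libraries were tested as if they were a target. They came from 8 random partitions of the same 19 libraries, so they overlap. In 37 of them no gene was called, and 30 targets lay above the highest count of these groups. The groups were drawn without regard to blocks of library numbers, while 5080 of 12790 genes differed between controls of the first and later blocks. They therefore do not stand for targets with every guide in 1 block, such as SRF, NSD1, GATA4 and STK11. Over all targets, 68682 pairs of a gene and a target were called, 38080 higher and 30602 lower.

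**Figure D1:**
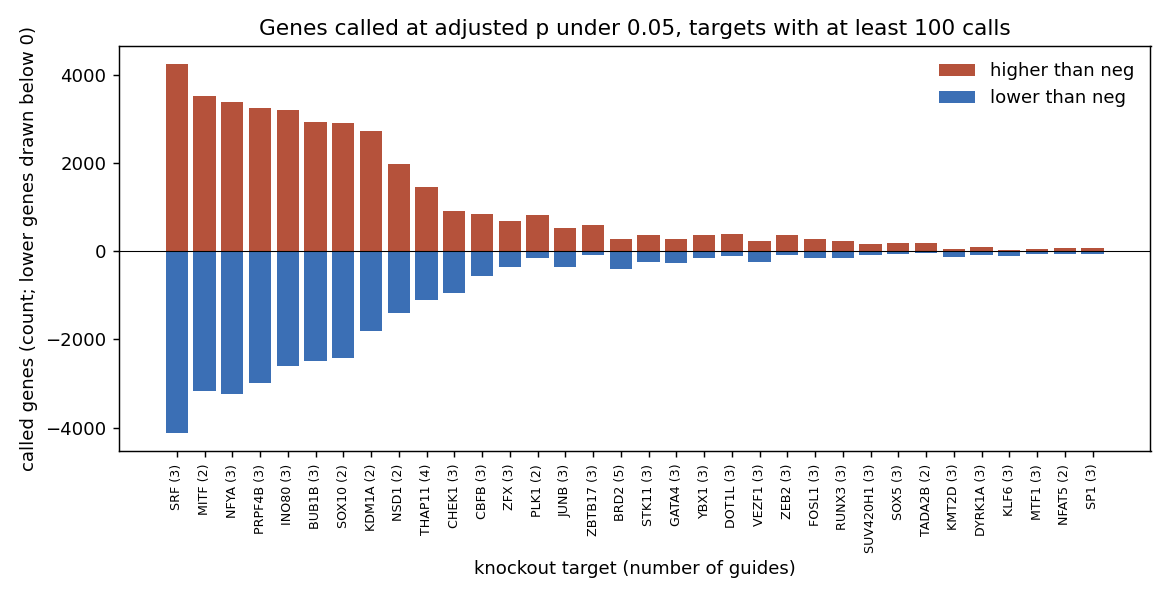
Number of called genes (y axis, genes) for each of the 34 targets with at least 100 (x axis, number of guides in brackets). Genes higher than in neg are drawn upward and lower genes downward. SRF has the longest bar, with 4239 higher and 4118 lower.

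Guides of 1 target were on average more alike than guides of different targets. The mean correlation across genes of the deviations from neg was 0.272 over pairs of guides with the same target, and 0.0655 over 25206 pairs of guides with different targets. The difference was 0.207 (permutation of guides over targets, p = 1e-04, the smallest that 10000 draws allow). Targets differed widely, with a mean correlation between guides from -0.178 in EGFR to 0.817 in MITF. Some targets, such as CSK at 0.017, lay below 0.0655. Libraries with nearby numbers in the titles were alike, so the comparison was also made between libraries from different blocks of numbers, where it was 0.228 over 140 pairs with the same target against 0.0167 over 16868 pairs. No gene separated WT from neg in the fit of all groups, where edgeR called 0 of 16635 genes, with 401 at unadjusted p under 0.05. With only neg and WT in the fit 1 gene was called, and DESeq2 called 2.

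NGFR and EGFR are the proteins by which the priming screen sorted cells, and their mRNAs were followed across all 82 targets. NGFR, the low-affinity neurotrophin receptor (chromosome 17, 47572655 to 47592370, hg19), had 2.51 ± 1.03 CPM in 10 neg libraries and 3.33 ± 1.54 CPM in 19 WT libraries. It rose in 11 targets and fell in 0, adjusted over the targets. After MITF knockout it reached 28.7 ± 13.9 CPM in 2 guides, with a log2 fold change of 3.46 ± 0.51. LATS2 had 9.23 ± 2.39 CPM, with 11.8, 8.85 and 7.05 CPM in its 3 guides and a log2 fold change of 1.81 ± 0.50. This passed over the targets (adjusted p = 0.00482) but not among all genes of the LATS2 contrast (adjusted p = 0.570). At log2 fold changes of 1.79 to 1.84 it was called among all genes in 5 alternatives: LATS2 and neg alone (adjusted p = 0.00113), DESeq2 (5.16e-07), no filter on low counts (2.75e-10), and without libraries under 2000000 counts (0.0328) or at the far end of the first principal component (2.70e-05). SOX10, NFYA, PRPF4B, BUB1B, CHEK1, ZFX, TADA2B, MTF1 and ZBTB17 were the other 9. Of the 11, all but LATS2, TADA2B and MTF1 had a library at the far end of the first principal component, where no control lay. Only 15 of the 82 targets had such a library. Without those libraries NGFR was at -0.10 in NFYA, and over the targets it was higher in 12 and lower in 1. The value for the checkpoint kinase CHEK1, 4.25 ± 0.53, rests on 1 guide far above the others, which had 4.43 and 4.64 CPM, and in ZFX and ZBTB17 only 1 of 3 guides lay above the neg mean.

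EGFR, the epidermal growth factor receptor (chromosome 7, 55086710 to 55279321), had 16.0 ± 1.86 CPM in neg and 17.6 ± 3.74 CPM in WT. It rose in 8 targets and fell in 9. The increases were small. CBFB, the partner subunit of RUNX transcription factors, gave 0.86 ± 0.17 and 29.3 ± 8.99 CPM, and the histone methyltransferase DOT1L gave 0.63 ± 0.17 and 24.8 ± 2.28 CPM, each in 3 guides. SUV420H1, EP300, TADA2B, MYBL1, KMT2D and BRD2, which act on chromatin or transcription, were the other 6. The largest decrease was -1.27 ± 0.27 after knockout of NFAT5, a transcription factor of the response to osmotic stress, and the kinase DYRK1A and the methyltransferase NSD1 gave -0.98 and -0.82. In the EGFR knockout itself EGFR had -0.37 ± 0.23 and was not called. AXL, a receptor kinase of drug-tolerant melanoma cells, rose in 10 targets and fell in 0. It had 0.342 ± 0.367 CPM in neg, a level from which a fall could hardly be called. MITF mRNA rose in 4 targets and fell in 1, CSK, while SOX10 mRNA fell in 4 and rose in 0.

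**Figure D2:**
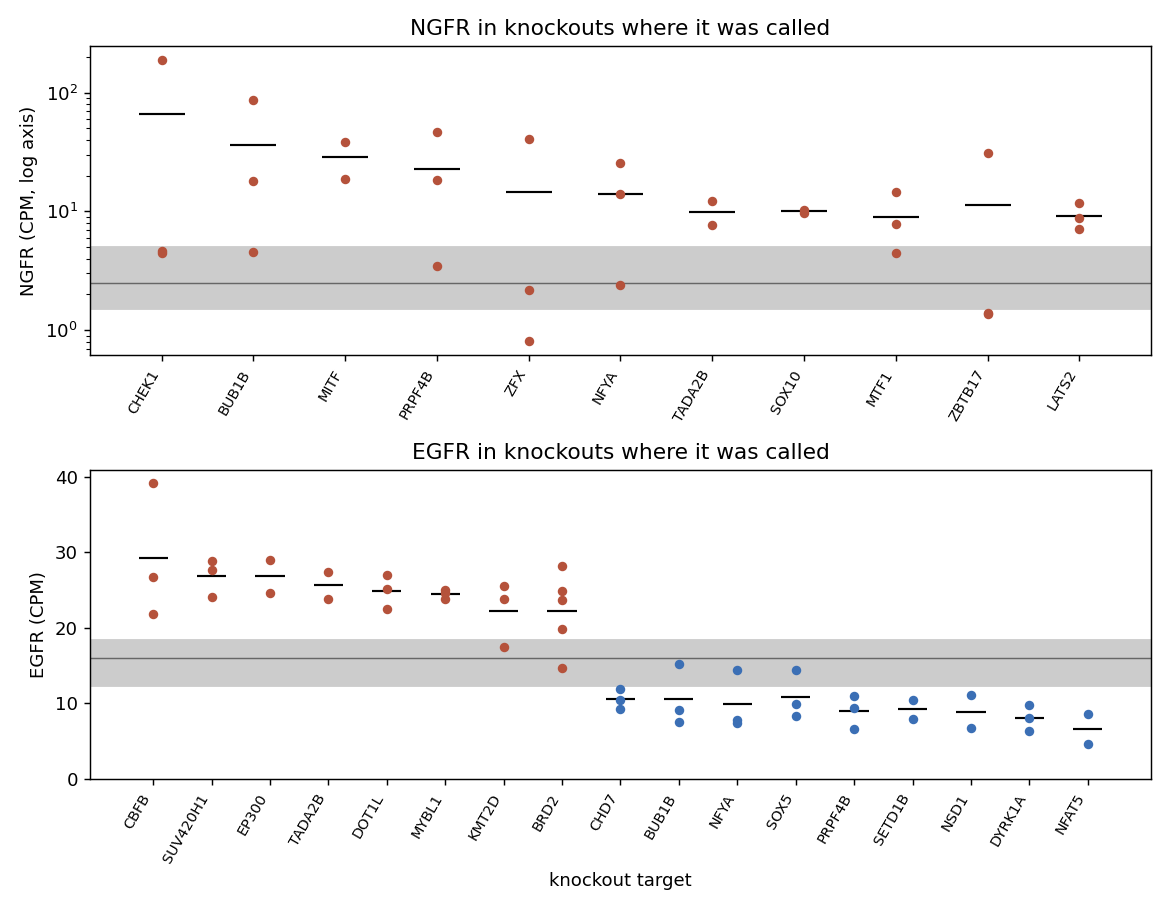
CPM of NGFR (top, log axis) and EGFR (bottom) in each guide (points) of the knockouts where the gene was called, with the mean of the guides (bar). The grey band is the range of the 10 neg libraries, up to 5.04 CPM for NGFR and 12.3 to 18.4 CPM for EGFR, and the line is their mean.

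Knockout of SOX10, the transcription factor that sets neural crest and melanocyte identity (chromosome 22, 38366693 to 38383429), called 5337 genes, 2911 higher and 2426 lower, in 2 guides. SOX10 mRNA itself was not called, at 774 ± 56.7 CPM after knockout and 804 ± 53.6 CPM in neg. The neuropilin NRP1 rose with a log2 fold change of 6.29 ± 0.73, from 0.0537 to 6.38 CPM. COL1A1, a chain of collagen I, rose with 4.74 ± 0.44, to 29.8 ± 30.2 CPM, and IGFBP7, a secreted growth factor binding protein, with 4.57 ± 0.51. SIRPB1, OLFML2B, SRGN, ITGA11 and SPOCK1 completed the 8 highest, at 6.14 to 4.06. The lowest were the noncoding RNA LINC00906 with -4.42 ± 0.85, IGSF9 with -3.94 and the actin-binding CORO2B with -3.93 ± 0.57, followed by RBMS3, ZNF853, MYO15B, SLAMF9 and C17orf77 down to -2.83. NGFR and AXL rose, with 1.94 ± 0.61 and 2.53 ± 0.81, while EGFR (0.27 ± 0.21) and MITF (0.16 ± 0.10) were not called.

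Of the 18 melanocyte differentiation genes, 11 fell after SOX10 knockout, 2 rose and 5 were not called, with the same counts adjusted over the list alone. The melanosome matrix protein PMEL fell from 14577 to 7303 CPM. TYRP1 and MLPH, a pigment enzyme and a melanosome transport protein, fell with -1.82 ± 0.48 and -1.22 ± 0.23, and the channel TRPM1 fell with -1.17 ± 0.19. In the extracellular matrix list 8 of 13 rose and 0 fell, and 9 when adjusted over the list alone, among them fibronectin FN1 (2.27 ± 0.29), COL6A3 (2.00 ± 0.40) and COL5A1 (4.49 ± 0.71). All 6 fibroblast markers tested rose, 6 over the list alone, with FAP at 4.46 ± 0.79 and decorin DCN at 1.57 ± 0.50, and levels of 2.00 and 2.47 CPM. Genes of mitosis rose in 20 of 20 cases, such as the cyclin CCNA2 (1.32 ± 0.24), AURKA (1.30), CENPE (1.28) and CDC20 (1.26). Genes of DNA replication rose in 19 of 20, with the nucleotide enzyme RRM2 at 1.40 ± 0.26, UHRF1 at 1.30, TYMS at 1.23 and CDC45 at 1.22. Of 25 cytosolic ribosome genes 22 fell and 23 over the list alone, RPS6, RPS8, RPL18 and RPL14 by -0.84 to -0.75.

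Smaller groups moved as well after SOX10 knockout. Cholesterol synthesis fell in 7 of 20, 8 over the list alone, led by HMGCS1 (-1.35 ± 0.37), PCSK9, MSMO1 and STARD4. Hypoxia and glycolysis fell in 7 of 18, 8 over the list alone, with 1 higher, and included BNIP3 (-0.89 ± 0.28), KDM3A and P4HA1; CA9, at 1.04 CPM in neg, had 0 counts in both guides. Immediate early genes rose in 7 of 16, 7 over the list alone, led by IER3 (1.47 ± 0.26), FOSL1, EGR3 and JUNB. All 9 lists were called by camera with the preset correlation, and none with an estimated correlation. The adjusted p was then 0.288 for melanocyte differentiation, 0.258 for extracellular matrix, 0.218 for fibroblast markers, 0.464 for mitosis, 0.382 for DNA replication, 0.358 for the ribosome, 0.836 for cholesterol synthesis, 0.796 for hypoxia and 0.648 for immediate early genes. Of the 5337 called genes, 638 rose and 904 fell over 2-fold, and 99.6% had the same sign in both guides. The call rests on the mean of these same guides and so favours such agreement, which is no separate support. The share was 99.4% in MITF and DOT1L, 100% in LATS2, 91.6% in SRF, 88.3% in NFYA, 82.1% in PRPF4B and 66.7% in CSK. Without guide 2, which lay far from controls on the first principal component, 974 genes were called. Without guide 1 the lists of extracellular matrix, fibroblast markers, cholesterol synthesis and immediate early genes were not called (adjusted p = 0.333, 0.196, 0.246 and 0.244), nor was hypoxia without guide 2 (0.293).

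Knockout of MITF, the master regulator of melanocytes (chromosome 3, 69788607 to 70017487), called 6698 genes, 3525 higher and 3173 lower, in 2 guides. Both guides lay at the far end of the first principal component of all libraries, at 43.2 and 62.2, where no control lay, and the correlation of the change with that of SRF knockout was 0.852. MITF mRNA was 1153 ± 628 CPM against 537 ± 32.9 CPM in neg. The matrix-associated ITIH5 rose most by the naming rule, with a log2 fold change of 6.21 ± 0.40. AXL rose with 4.99 ± 0.57, from 0.342 to 12.5 CPM, the EGFR ligand TGFA with 4.94 ± 0.42 and the WNT antagonist DKK1 with 4.30 ± 0.82. SRGN, FST, MGP and PMEPA1 lay between 4.84 and 3.99. COL20A1 (-5.27 ± 0.94), the nucleoside transporter SLC28A3 (-5.15 ± 0.98), LINC00906, the retinol dehydrogenase RDH8 (-4.24 ± 0.55), IGSF9, ADHFE1, ESPN and SNCB (-3.22 ± 0.58) were the lowest. SOX10 (0.10 ± 0.10) and EGFR (0.07 ± 0.22) were not called.

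Drug resistance markers rose after MITF knockout in 9 of 17 and fell in 2, or 9 and 3 over the list alone. Beside AXL and NGFR (3.46 ± 0.51), the plasminogen activator inhibitor SERPINE1 rose with 3.75 ± 0.56 and the growth factor PDGFC with 2.95 ± 0.50. Melanocyte differentiation genes fell in 12 of 18 and rose in 3, or 13 and 3 over the list alone, with TRPM1 at -1.61 ± 0.20, MLPH at -1.58, PMEL at -1.25 ± 0.23 and TYRP1 at -1.25 ± 0.44. Mitosis genes rose in 18 of 20, 20 over the list alone, with BIRC5 at 1.49 ± 0.24, AURKA, CDC20 and UBE2C. DNA replication genes rose in 18 of 20, 19 over the list alone, with CDC45 at 1.58 ± 0.22, RRM2, UHRF1 and TYMS. The immediate early genes IER3, EGR1, EGR3 and FOS rose by 1.69 to 1.09, and 7 of 16 in that list were higher and 1 lower, with the same counts over the list alone. In the extracellular matrix list 6 of 13 rose, also over the list alone, the collagens COL1A2, COL5A1, COL1A1 and COL5A2 by 3.29 to 1.70. Hypoxia and glycolysis fell in 11 of 18, 12 over the list alone, with 1 higher; NDRG1 fell with -2.14 ± 0.56, PDK1 with -1.39 ± 0.34 and BNIP3 with -1.37, and CA9 had 0 counts in both guides. The ribosomal genes RPS6, RPL10, RPL18 and RPL13 fell by -0.62 to -0.50, with 12 of 25 lower, also over the list alone. None of these 8 calls held with an estimated correlation, where the adjusted p was 0.610 for drug resistance, 0.349 for melanocyte differentiation, 0.591 for mitosis, 0.396 for DNA replication, 0.494 for immediate early genes, 0.610 for extracellular matrix, 0.699 for hypoxia and 0.754 for the ribosome. Without guide 3 of MITF 3653 genes were called. Without guide 2 the lists of drug resistance markers, extracellular matrix and immediate early genes were not called (adjusted p = 0.188, 0.170 and 0.0601), nor were the first 2 with WT added to the control (0.0626 and 0.0554).

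**Figure D3:**
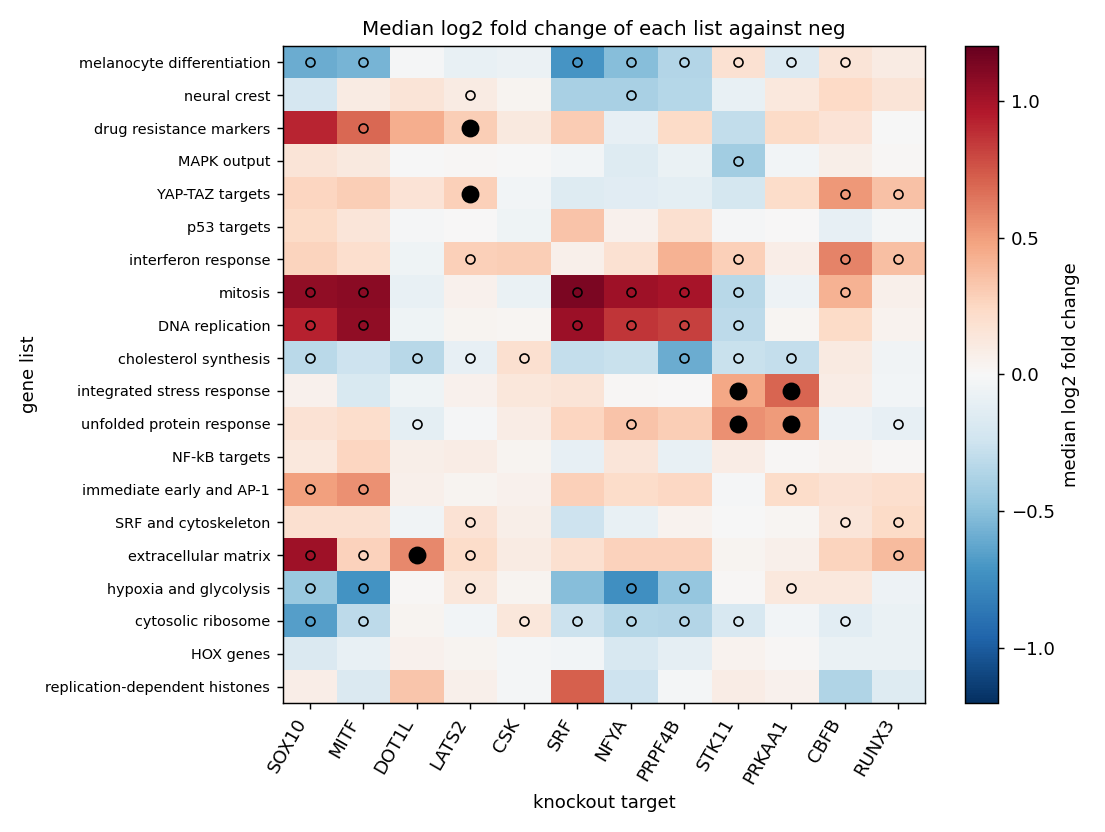
Median log2 fold change of gene lists (rows) in 12 knockouts (columns), in colour. An open circle marks a list called with the preset correlation and a filled circle a list that was also called with an estimated correlation, as the extracellular matrix list in DOT1L.

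DOT1L, the methyltransferase of histone H3 lysine 79 (chromosome 19, 2163932 to 2232577), was a target of the priming screen, and its knockout mostly raised genes. Of 482 called genes 380 rose and 102 fell, with 215 higher and 2 lower over 2-fold. Among them 99.4% had the same sign in all 3 guides, which the call from the mean of these guides favours. DOT1L mRNA fell with -0.37 ± 0.11 over the targets and had an adjusted p of 0.0544 among all genes. ARHGEF16, an exchange factor for Rho-family GTPases, rose with 2.84 ± 0.33. The neuronal genes SRRM3 and SLITRK2 rose with 2.46 ± 0.31 and 2.43 ± 0.30, and the calcification inhibitor MGP rose with 2.32 ± 0.25 to 51.7 ± 27.6 CPM. PRSS33, DACT1, TRNP1 and C1orf95 were between 2.34 and 2.22. The lowest were RNF182 (-1.14 ± 0.20), MCTP1, PPM1L, the serotonin receptor HTR7, SYNC, COL6A5, KCNE4 and COL19A1 (-0.80 ± 0.23). EGFR rose with 0.63 ± 0.17; NGFR (0.67 ± 0.57), AXL (-0.20 ± 0.94), MITF (-0.04 ± 0.08) and SOX10 (-0.07 ± 0.09) were not called.

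In the extracellular matrix list 4 of 13 genes rose after DOT1L knockout and 8 when adjusted over the list alone. FN1 rose with 1.42 ± 0.26, from 699 to 1873 CPM, SPARC with 0.42 ± 0.10, COL6A2 with 0.57 ± 0.15 and COL5A1 with 3.11 ± 0.71 at 1.15 CPM. This call held with an estimated correlation (adjusted p = 0.00858). Of the 6 fibroblast markers 1 rose, DCN with 1.61 ± 0.39 at 2.75 CPM, and 5 over the list alone (adjusted p = 0.0882 with an estimated correlation). Cholesterol synthesis was called lower with 1 of 20 members called, the LDL receptor LDLR at -0.43 ± 0.13, and 10 over the list alone (adjusted p = 0.349 with an estimated correlation). The unfolded protein response was called lower with 0 of 15 members called, also over the list alone, and the 3 immune cell markers higher with 0 called and 3 over the list alone (adjusted p = 0.480 and 0.135 with an estimated correlation). The number of called genes depended on the guides and the fit. It was 140 higher and 8 lower with guide 2 of all targets left out, which also changes the shared fit. It was 496 higher and 250 lower in a fit of DOT1L and neg alone, and 506 higher and 323 lower with DESeq2.

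LATS2 is a kinase of the Hippo pathway that restrains the coactivators YAP and TAZ (chromosome 13, 21547175 to 21635725), and after its knockout the list of YAP-TAZ targets was called higher, with 2 of 20 members called. MYOF, a membrane repair protein, rose from 28.6 ± 7.59 to 72.2 ± 21.0 CPM, with a log2 fold change of 1.32 ± 0.26 (adjusted p = 0.00618, 3 guides). CRIM1, a membrane protein that binds BMP ligands, rose with 1.96 ± 0.36 (adjusted p = 0.00190) and the matrix protein MATN2 with 1.42 ± 0.31 (adjusted p = 0.0352). These were 3 of 4 called genes, all higher in every guide. The other, KIAA1755, with 1.57 ± 0.32, was chosen after its values were seen. LATS2 mRNA had -0.07 ± 0.11, EGFR 0.12 ± 0.18, AXL 1.66 ± 0.73, MITF -0.02 ± 0.08 and SOX10 -0.03 ± 0.09, and none of these was called.

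Of 20 YAP-TAZ targets tested, 2 rose after LATS2 knockout, CRIM1 and MYOF, and the same 2 when adjusted over the list alone. The list was called higher, also with an estimated correlation (adjusted p = 0.0111). Drug resistance markers were called higher with 0 of 17 members called and 4 over the list alone, and this held with an estimated correlation (adjusted p = 0.0122). AXL, CYR61 and NT5E are in both lists. Neural crest (0 of 15 called, 2 over the list alone), interferon response (0 of 22 and 0), SRF and cytoskeleton (0 of 16 and 1), extracellular matrix (0 of 13 and 4) and hypoxia (0 of 18 and 0) were called higher with the preset correlation alone, as were cholesterol synthesis (0 of 20 and 0) and the 3 immune cell markers (0 and 0) lower. With an estimated correlation their adjusted p was 0.331, 0.0910, 0.0797, 0.0828, 0.705, 0.699 and 0.331. MATN2, which had 0.86 ± 0.24 in WT against neg, was not called with WT in the control or with any 1 guide left out, and MYOF was not called without guide 1 or without guide 2. No filter on low counts gave 45 called genes, a fit of LATS2 and neg alone 17 and DESeq2 37. The lists of YAP-TAZ targets and drug resistance markers stayed called without any 1 guide, while neural crest was not called with WT in the control (adjusted p = 0.126), nor hypoxia and immune cell markers without guide 1 (0.0742 and 0.347), nor hypoxia and cholesterol synthesis without guide 2 (0.111 and 0.871).

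CSK is the kinase that inhibits SRC family kinases (chromosome 15, 75074421 to 75095538). Its own mRNA fell with -0.71 ± 0.15 in the mean of 3 guides, of which 2 lay below neg. This call was lost without guide 1 (-0.58, adjusted p = 0.251), without guide 2 (-0.39, 0.360), in a fit of CSK and neg alone (0.235), with DESeq2 (0.0852) and with the 1.5-fold threshold. Of 12 called genes 11 rose and CSK alone fell. CCDC85B rose with 0.93 ± 0.15, from 200 to 393 CPM, and the lysosomal cysteine transporter MFSD12 with 0.61 ± 0.11. H1FX, PTMS, TMSB10, HMG20B, GUK1 and FAM50A rose by 0.60 to 0.35. UBB, BRI3 and FTH1, named after their values were seen, rose with 0.61, 0.46 and 0.67 and were not higher in every guide. NGFR (1.38 ± 0.63), EGFR (-0.30 ± 0.22), AXL (-1.34 ± 1.60), MITF (-0.29 ± 0.09) and SOX10 (0.01 ± 0.09) were not called among all genes, and MITF passed over the targets. Without libraries at the far end of the first principal component NGFR and MITF were called among all genes (adjusted p = 0.0381 and 0.0184), as were NGFR with no filter on low counts (0.00985) and MITF with DESeq2 (0.0425). In the other alternatives neither was called among all genes. Cholesterol synthesis and the cytosolic ribosome were called higher with 0 members called, and 1 and 0 over the list alone; the adjusted p was 0.720 and 0.811 with an estimated correlation. Most of these calls rest on guide 3, a library of 507726 counts, without which 1 gene was called. A fit of CSK and neg alone with edgeR called 0 genes, with 1361 at unadjusted p under 0.05, and DESeq2 called 76, and the ribosome list was not called without guide 1 (adjusted p = 0.756).

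The 3 further knockouts with the most called genes, SRF, NFYA and PRPF4B, shared much of their change with each other and with other targets. Correlations across genes of log2 fold changes, each against a separate part of the neg libraries, were 0.911 for NFYA and SRF, 0.897 for PRPF4B and SRF and 0.891 for NFYA and PRPF4B. Between groups of 3 WT libraries the highest of 750 such values was 0.263. The first principal component of all libraries held 37.0% of the variance, and 22 knockout libraries from 15 targets lay at its far end, past a gap between 31.8 and 43.2. No control lay there, the highest neg library being at -3.98. Every guide lay past the gap in SRF and MITF, while in 13 targets some guides did and others did not. In NFYA and PRPF4B guide 3 lay below the gap, at 10.1 and 5.36, against 83.2 and 70.4 for the other guides of NFYA, and 73.0 and 75.3 for those of PRPF4B. In SOX10, guide 2 lay past the gap and guide 1 at 31.8.

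**Figure D4:**
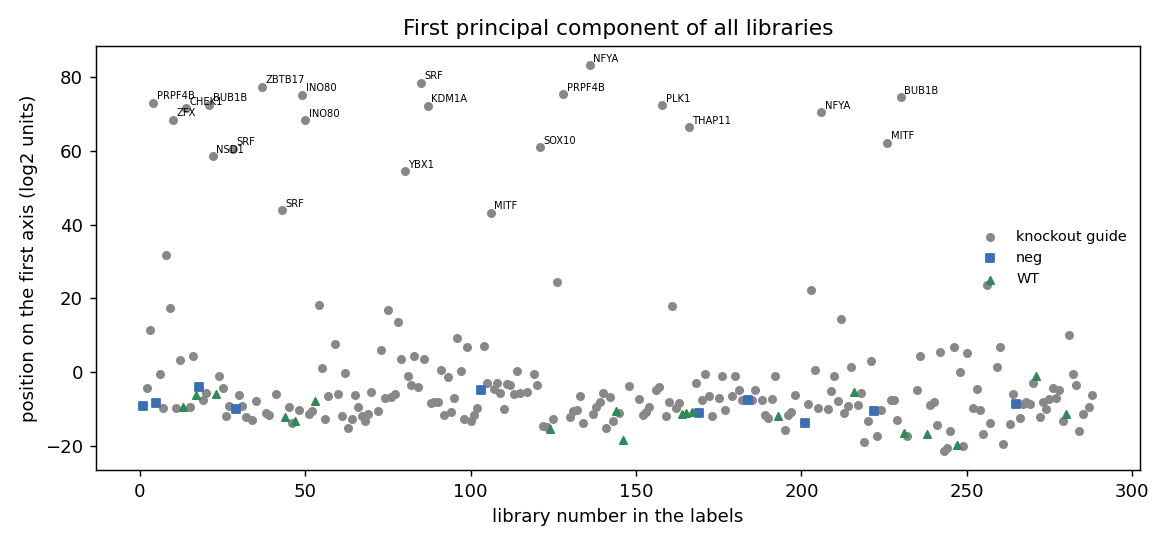
Position of each library on the first principal component (y axis, log2 units) against the library number in the titles (x axis). Points are knockout guides, squares neg and triangles WT; the 22 labelled libraries lie at 43.2 or above, and the highest control at -1.10.

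SRF mRNA (chromosome 6, 43139007 to 43149244) fell with -0.68 ± 0.12 in 3 guides. The inhibitors of differentiation ID1 and ID3 rose after SRF knockout with 3.30 ± 0.58 and 2.67 ± 0.47, the noncoding RNA BCYRN1 with 3.55 ± 0.47 and the KIT ligand KITLG with 2.70 ± 0.49. The myelin protein MPZ rose from 7.22 to 47.2 CPM, and TSPAN13, the imprinted RNA H19 and METTL7B were at 2.61 to 2.57. LINC00906 fell with -4.09 ± 0.67, followed by MYO15B, PDZD2, KIAA1244, SLC28A3, RBMS3, EBF4 and C17orf77, down to -3.19. DNA replication genes rose in 20 of 20, as over the list alone, with RRM2 at 1.66 ± 0.22, GINS2, TYMS and PCNA at 1.52 ± 0.20. Mitosis genes rose in 18 of 20, 18 over the list alone, with CDK1 at 1.69 ± 0.24, BIRC5, CDC20 and AURKA. Melanocyte differentiation genes fell in 12 of 18 and rose in 4, with the same counts over the list alone; TYRP1 was at -1.75 ± 0.40, MLPH at -1.29 ± 0.20, CAPN3 at -1.22 and OCA2 at -1.70 ± 0.73. Ribosomal genes fell in 12 of 25, also over the list alone, RPL3, RPL18, RPL10 and RPS8 by -0.63 to -0.53. The adjusted p was 0.409 for DNA replication, 0.571 for mitosis, 0.518 for melanocyte differentiation and 0.847 for the ribosome with an estimated correlation. No other list was called after SRF knockout. The list of SRF and cytoskeleton and the list of immediate early and AP-1 genes were thus not called. AXL (1.90 ± 0.79) and MITF (0.20 ± 0.08) rose and SOX10 (-0.40 ± 0.09) fell; NGFR (1.24 ± 0.59) and EGFR (-0.39 ± 0.20) were not called. All 3 libraries of SRF came from the first block of library numbers. With the block as a covariate, 92.4% of the called genes stayed called. With guide 2 of all targets left out, the lists of melanocyte differentiation and the ribosome were not called for SRF (adjusted p = 0.0601 and 0.792).

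NFYA is the DNA-binding subunit of the CCAAT-box factor NF-Y (chromosome 6, 41040713 to 41070142), and its own mRNA was not called, at 0.21 ± 0.16. After its knockout ID1 rose with 3.88 ± 0.56, BCYRN1 with 2.69 ± 0.53, the transcription factor ATOH8 with 2.55 ± 0.44 and NGFR with 2.44 ± 0.53, while TSPAN13, DLEU2, the centromere protein CENPW and FLVCR2 were at 2.39 to 2.19. LINC00906 (-3.39 ± 0.67), SLC28A3, RBMS3, PLCB1, ZNF853, LINGO1, CORO2B and FAM65B (-2.36 ± 0.33) were the lowest. The unfolded protein response rose in 10 of 15 and fell in 1, also over the list alone, with the chaperones SDF2L1 (1.13 ± 0.22), MANF (0.95 ± 0.17), PDIA4 and CRELD2. Mitosis and DNA replication rose in 18 of 20 each, also over the list alone, with CDK1 at 1.37 ± 0.24, BIRC5, AURKA and UBE2C, and RRM2 at 1.44 ± 0.23, GINS2, PCNA and CDC6. Melanocyte differentiation fell in 9 of 18 and rose in 2, also over the list alone, with MLPH at -1.29 ± 0.20, GPNMB, CAPN3 and TYR. In the neural crest list 10 of 15 fell and 3 rose, also over the list alone. CDH19 fell with -1.43 ± 0.26, while AQP1 (3.07 ± 0.89, at 1.01 CPM), NGFR and MPZ (2.18 ± 0.31) rose, and the median was -0.39 while the mean was 0.04 and the test gave lower. Hypoxia genes fell in 11 of 18, also over the list alone, with NDRG1 at -2.09 ± 0.47, CA9 at -2.11 ± 0.86, SLC2A1 and ANKRD37, and ribosomal genes in 17 of 25, 17 over the list alone, with RPL18 at -0.69 ± 0.13, RPS16, RPL10 and RPL3. With an estimated correlation the adjusted p was 0.571 for the unfolded protein response, 0.598 for mitosis, 0.480 for DNA replication, 0.602 for melanocyte differentiation, 0.464 for neural crest, 0.796 for hypoxia and 0.788 for the ribosome. AXL rose (2.34 ± 0.79), EGFR (-0.63 ± 0.22) and SOX10 (-0.32 ± 0.09) fell, and MITF (0.16 ± 0.08) was not called. With guide 3 alone, after libraries at the far end of the first principal component were left out, 28 genes were called. NGFR and AXL were then at -0.10 and -0.37 and were not called. With guide 3 of all targets left out, the unfolded protein response, melanocyte differentiation, neural crest, hypoxia and ribosome lists were not called for NFYA (adjusted p = 0.0863, 0.0971, 0.0883, 0.0560 and 0.116).

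PRPF4B, a kinase of the spliceosome (chromosome 6, 4021501 to 4065217), had mRNA at 0.01 ± 0.09 in its own knockout, which was not called. ID3 rose with 3.71 ± 0.46, SRGN with 3.64 ± 0.74, COL1A1 with 3.10 ± 0.52 and NGFR with 2.97 ± 0.52, and IGFBP7, H19, BCYRN1 and the annexin ANXA1 were at 3.01 to 2.67. LINC00906 (-2.91 ± 0.65), IGSF9, CORO2B, the microtubule protein DCX, EBF4, SLC28A3, STON1 and FAM65B (-2.29 ± 0.33) were the lowest. Cholesterol synthesis fell in 13 of 20 and 15 over the list alone, with CYP51A1 at -1.63 ± 0.49, HMGCS1 at -1.09 ± 0.31, PCSK9 and STARD4. Mitosis and DNA replication rose in 18 of 20 each, also over the list alone, with BIRC5 at 1.42 ± 0.23, CDK1, AURKB and AURKA, and RRM2 at 1.51 ± 0.23, TYMS, GINS2 and CDC45. Melanocyte differentiation fell in 8 of 18 and rose in 3, or 9 and 3 over the list alone, with GPNMB at -0.85 ± 0.12, MLPH, TYR and PMEL. Hypoxia fell in 10 of 18 and rose in 1, or 11 and 1 over the list alone, with NDRG1 at -1.74 ± 0.46, CA9 at -2.70 ± 1.03, SLC2A1 and VEGFA. Ribosomal genes fell in 16 of 25, 16 over the list alone, with RPL18 at -0.70 ± 0.13, RPL3, RPS16 and RPL10. The adjusted p was 0.648 for cholesterol synthesis, 0.576 for mitosis, 0.494 for DNA replication, 0.653 for melanocyte differentiation, 0.829 for hypoxia and 0.734 for the ribosome with an estimated correlation. AXL (2.97 ± 0.76) and MITF (0.20 ± 0.08) rose, and EGFR (-0.77 ± 0.23) and SOX10 (-0.35 ± 0.09) fell. With guide 3 of PRPF4B alone, chosen in the same way, 23 genes were called. AXL and MITF were then at -0.05 and -0.01 and were not called, nor was the hypoxia list (adjusted p = 0.599), which also ended without guide 1 (0.0843) or guide 2 (0.0632), as melanocyte differentiation did without guide 1 (0.0678) or guide 3 (0.0924).

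Across all 82 targets, 393 of 1886 tests of a list in a knockout were called with the preset correlation, 177 of them lower and the others higher, and 9 with an estimated correlation. Cholesterol synthesis was called lower in 39 targets and higher in 2, the cytosolic ribosome lower in 39 and higher in 15, and melanocyte differentiation lower in 25 and higher in 5. Mitosis was called higher in 33 and lower in 16, DNA replication higher in 25 and lower in 10, and the interferon response higher in 23 and lower in 1. Higher and lower counts were 14 and 9 for the unfolded protein response, 9 and 3 for the integrated stress response, 11 and 16 for hypoxia and glycolysis, 11 and 4 for MAPK output, 10 and 4 for YAP-TAZ targets and 12 and 0 for immediate early genes. They were 7 and 2 for neural crest, 7 and 2 for drug resistance markers, 12 and 1 for extracellular matrix, 5 and 2 for SRF and cytoskeleton, 1 and 0 for p53 targets and 0 and 1 for NF-kB targets. HOX genes had 1 and 1, histones 2 and 1, fibroblast markers 8 and 0, keratinocyte markers 0 and 0 and immune cell markers 3 and 1. Between WT and neg, mitosis was called lower and the ribosome higher with the preset correlation, at medians of -0.13 and 0.09, and the adjusted p was 0.885 and 0.711 with an estimated correlation.

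Knockouts of known partners were compared with each other as 10 pairs fixed in advance. The correlation across genes was 0.855 for SOX10 and MITF (covariance 0.313) and 0.590 for CBFB and RUNX3 (covariance 0.0494). CBFB and RUNX3 were each other's closest knockouts, while MITF had 0.852 with SRF and 0.844 with BUB1B, which lie within the spread of 0.0587 between pairs of guides of its value with SOX10. The correlation was 0.219 for the coactivators TADA2B and EP300 and 0.173 for the kinases STK11 and PRKAA1, both above the 95th percentile of 0.128 between groups of WT libraries and at the 91.7th and 89.8th percentile of all pairs of targets, while the median covariance between groups of WT libraries was -0.00219. Without guide 2 the value of TADA2B and EP300 was 0.125, and without guide 3 that of STK11 and PRKAA1 was 0.0874, both below that level. The 6 other pairs did not exceed that level: 0.124 for RAF1 and MAPK1 (-0.0856 to 0.286 with 1 guide left out, and 0.376 with WT libraries as controls, where the level of 0.128 does not apply and the percentile among all pairs of targets went from 86.4 to 91.8), 0.0507 for JUN and FOSL1, -0.0808 for CSK and SRC, -0.0895 for KDM1A and GFI1, -0.0931 for PTK2 and SRC and -0.117 for EGFR and RAF1. The SOX10 and MITF value ranked 11 among 3321 pairs of targets, and pairs of SRF, NFYA, PRPF4B, BUB1B and INO80 ranked above it.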

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

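The tests of the silent targeted genes in this part were chosen after the counts had been seen.

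Total counts of 1 BRD2 library, from guide 4, lay far from the other libraries of its group. The library had 3256559 counts, and the nearest of the 4 others had 4121451. A total of 31 values were tested in 4 groups of 4 to 10 libraries, and chance marks about 1 in 20 groups in this way.

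A signal also appeared in genes that were too low to be tested. NR1I2 had 2.78 CPM in its own knockout, from 2 counts in 1 guide, and 0 in neg. ZFP57 had 1.10 CPM over its 3 guides, from 6, 2 and 3 counts, and 0.0158 CPM in neg. Outside their own knockouts, NR1I2 had 9 counts and ZFP57 had 3 over all libraries.

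Other targeted genes that these cells express at under 1 CPM had counts in their own knockouts as well. FEZF2 had 6, 10 and 4 counts in its own guides, MAFA had 12, 15 and 4, FOXC2 had 4, 10 and 1 and LHX1 had 0 and 8. The pooled CPM of each gene was compared with that of guides drawn at random from other targets. For FEZF2, MAFA and ZFP57 none of 10000 draws reached it, which gives p = 1e-04, the smallest that these draws allow. The adjusted p was 2.33e-04 for these 3, 7e-04 for FOXC2 and 0.0374 for LHX1, and it was 0.260 for GFI1 and 0.371 for VDR, so 5 of 7 targets passed. NR1I2 has 1 guide and was not tested.

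For FEZF2 and ZFP57 the tables argue against reads spilling over from other libraries of the table, since at most 11 of the other libraries had a count of either gene and none had more than 1. MAFA, FOXC2 and LHX1 had counts in at least 77 other libraries, and 1 other library had 9 counts of LHX1, more than its own guides, so spill-over stays open for these 3. For MAFA and ZFP57 activation of the whole region would raise neighbours, and of 43 tested genes within 500000 bases 0 were higher and 1 lower at unadjusted p under 0.05 in edgeR, the one tool run on them, with medians of -0.02 for both. FEZF2 and FOXC2 had 6 tested neighbours, too few to decide, and none was looked up for LHX1. Reads from the guide construct could account for the 85 counts of these 5 genes and cannot be told apart from transcripts, because the table does not give positions within a gene, and no biological explanation was tested.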

How the results depend on the processing

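The tests without libraries under 1000000 counts, without libraries at the far end of the first principal component and with DESeq2 on WT were chosen after the data had been seen; all others were fixed before the data were examined. No paired analysis was possible because the replicate numbers only number the guides of a target. Of 31 main results, 3 held under each alternative run on them, with a kept call or a count within 1.5 times: agreement between guides and the numbers of targets whose own mRNA fell and rose. The correlation of RAF1 and MAPK1 changed sign without guide 1, but moved by less than its spread of 0.253 between pairs of guides. For genes named in the report and in the other observations, 430 values had 5474 alternatives, of which 4944 kept direction and side of the threshold, 488 lost the call, 38 gained it and 4 reversed. The 1.5-fold threshold accounts for 156 of the 488 and a guide left out for 167. For called lists, 95 of 321 alternatives lost the call and the others kept it.

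Without the 22 libraries at the far end of the first principal component, called genes were 3106 in SOX10, 28 in NFYA and 23 in PRPF4B, each with 1 guide left, and 24431 over all targets. The lone guide is assumed to vary like the other groups, and fewer libraries were compared. MITF and SRF had no guide left and gave no value. DOT1L had 262 lower genes, LATS2 15 called genes and CSK 127, against 102, 4 and 12 in the main fit. None of the 22 libraries was from DOT1L, LATS2, CSK or neg. The same libraries were therefore compared, and these counts changed with the shared fit. Which part of that fit changed them was not tested. NGFR was lower in 1 target, and the cause was not tested. In the same setting 4 values reversed: NGFR in NFYA was -0.10, AXL in NFYA -0.37, AXL in PRPF4B -0.0471 and MITF in PRPF4B -0.0094.

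The 1.5-fold threshold asks for larger changes and left 11 targets with at least 100 called genes and 8186 pairs of a gene and a target. Called genes were then 439 in SOX10, 1320 in MITF, 86 higher in DOT1L, 2168 in SRF, 750 in NFYA and 618 in PRPF4B. LATS2, CSK and the lower genes of DOT1L had 0 with glmTreat of edgeR, with 71, 108 and 31 at unadjusted p under 0.05. In a fit of 1 target and neg alone DOT1L had 250 lower, LATS2 17 called and CSK 0, with 1361 for CSK at unadjusted p under 0.05, and DESeq2 gave 323, 37 and 76. No filter on low counts gave 45 in LATS2, 32 in CSK and 1 between WT and neg, where a fit of the controls alone gave 1 and DESeq2 gave 2. With neg and WT as control LATS2 had 2 and CSK 25, and with WT alone 2 and 21, and 63 lower in DOT1L. A minimum of 2000000 counts gave 7 in LATS2 and 1 in CSK, and 1000000 counts gave 1 in CSK, since its guide 3 was left out. RLE scaling gave 22 in CSK, and the block covariate gave 71 in CSK and 155 lower in DOT1L. The cause was not tested.

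An estimated correlation left 8 higher and 1 lower list of the 393. Over the same tests fry called 105 higher and 66 lower lists, how many of them are among the 393 was not counted, and the cause was not tested. With only the genes called in either knockout, the correlation was 0.383 for STK11 and PRKAA1, 0.867 for CBFB and RUNX3, 0.480 for JUN and FOSL1 and 0.410 for TADA2B and EP300, on fewer genes. With odd and even WT libraries as controls it was 0.325 for STK11 and PRKAA1, 0.188 for JUN and FOSL1, 0.0866 for PTK2 and SRC, 0.376 for RAF1 and MAPK1, 0.175 for EGFR and RAF1, 0.0145 for KDM1A and GFI1 and 0.309 for TADA2B and EP300. Against all pairs of targets compared in the same way these pairs did not all rise: the percentile went from 89.8 to 89.5 for STK11 and PRKAA1, 75.9 to 72.4 for JUN and FOSL1, 37.2 to 49.3 for PTK2 and SRC, 30.7 to 69.5 for EGFR and RAF1, 86.4 to 91.8 for RAF1 and MAPK1, 38.1 to 29.7 for KDM1A and GFI1 and 91.7 to 88.5 for TADA2B and EP300, and the cause was not tested.

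Leaving out 1 guide number at a time, in all targets at once, gave ranges from fewer samples. Targets with at least 100 called genes ran from 25 to 34 and pairs of a gene and a target from 41205 to 71826. Called genes ran from 974 to 4560 in SOX10, 3653 to 4721 in MITF, 140 to 392 higher and 8 to 135 lower in DOT1L, 1 to 2 in LATS2, 1 to 133 in CSK, 6986 to 7727 in SRF, 2614 to 7960 in NFYA and 1645 to 7914 in PRPF4B. NGFR was higher in 7 to 13 targets and lower in 0, EGFR higher in 5 to 8 and lower in 5 to 9. The targeted gene fell in 30 to 39 and rose in 9 to 13 targets. Correlations ran from 0.721 to 0.850 for SOX10 and MITF, 0.0874 to 0.181 for STK11 and PRKAA1, 0.491 to 0.608 for CBFB and RUNX3, -0.116 to 0.140 for JUN and FOSL1, -0.124 to 0.114 for CSK and SRC, -0.146 to 0.0114 for PTK2 and SRC, -0.0856 to 0.286 for RAF1 and MAPK1, -0.173 to 0.114 for EGFR and RAF1, -0.108 to -0.0116 for KDM1A and GFI1 and 0.125 to 0.201 for TADA2B and EP300.

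Depth limits weakly expressed genes most. At the median of 3331023 counts a gene at 1 CPM has a few counts per library, and NGFR, at 2.51 CPM in neg, is near that level.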

Other observations

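The splits of DOT1L, LATS2, CSK, SRF, NFYA, PRPF4B and WT and the tests of dividing cells, depth and RNA quality in this part were tests chosen after the results had been seen, and the 4 knockouts and their genes described first were also chosen after their values were seen.

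CBFB and RUNX3 encode 2 subunits of 1 transcription factor, and their knockouts called 1397 and 400 genes, with 845 and 237 higher. CBFB mRNA fell in its own knockout with a log2 fold change of -0.95 ± 0.15, and RUNX3 mRNA had -0.37 ± 0.13. The growth factor FGF5 rose with 7.43 ± 0.30 after CBFB knockout, from 0.554 CPM in neg, and with 4.83 ± 0.36 after RUNX3 knockout. TYRP1 rose with 5.30 ± 0.21 and 2.45 ± 0.24, the actin-bundling FSCN1 with 5.24 ± 0.22 and 2.77 ± 0.26 and the interferon-induced OASL with 2.85 ± 0.29 and 2.38. SPTBN2, BMP7 and GPC6 fell by -2.56, -2.18 and -2.40 after CBFB knockout and by -2.18, -2.29 and -2.35 after RUNX3 knockout. RUNX1 rose with 2.12 ± 0.14 after RUNX3 knockout, from 27.1 to 117 CPM. Both knockouts raised 202 genes and lowered 138, where chance gives 12.0 and 5.41 of 16635, and 0 genes went in opposite directions. Part of this excess may come from the shared neg libraries, though the correlation against separate parts of neg was also 0.590, and at least 0.491 when 1 guide was left out. With guide 1 of all targets left out 856 genes were called for CBFB, and with guide 2 left out the count of RUNX3 also fell by over 1.5 times.

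In fits of CBFB and neg alone, other splits of the libraries called at most 237 genes against 1919 in the real split, and 1 of 100 splits, the real one, reached that number. For RUNX3 the highest other split was 3 against 674, also 1 of 100. This is the smallest share that 100 splits can give, so chance is unlikely for each taken alone but not excluded. The count of splits also does not allow for choosing these knockouts after their values were seen.

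STK11 is the kinase that activates AMPK, and PRKAA1 encodes a catalytic subunit of AMPK. Their knockouts called 611 and 69 genes, at least 367 and 26 when 1 guide was left out. The unfolded protein response was called higher in both, with 8 and 7 of 15 members called and 11 and 14 when adjusted over the list alone, and it held with an estimated correlation (adjusted p = 2.91e-06 and 7.02e-10). The integrated stress response was called higher in both as well, with 7 and 5 of 15 members called and 10 and 11 over the list alone (adjusted p = 0.00597 and 7.97e-05 with an estimated correlation). ASNS rose with 0.88 ± 0.14 and 1.01 ± 0.14, and HSPA5 with 0.91 ± 0.10 and 0.82. In STK11 knockout the pigment enzyme DCT rose with 1.58 ± 0.19, from 506 to 1514 CPM, and NFATC2 fell with -2.10 ± 0.22. Both knockouts raised 43 genes and lowered 6, where chance gives 1.26 and 0.175, and 1 gene went in opposite directions. Part of this excess may come from the shared neg libraries, and the correlation against separate parts of neg, 0.173, was 0.0874 without guide 3. In fits with neg alone, other splits called at most 6 genes against 1161 for STK11 and at most 6 against 203 for PRKAA1, each in 1 of 100 splits. The choice of these knockouts is again not allowed for, and all 3 guides of STK11 lay in the last block of library numbers, which random splits do not mimic, so for STK11 the splits do not exclude an effect of the block. With the block as a covariate 861 genes were called for STK11 and 87 for PRKAA1.

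For the 8 knockouts of the report, other splits were drawn where a target had 3 guides, so SOX10 and MITF have none. For DOT1L, which was fixed by name, 1 of 100 splits, the real one, reached 746 genes and the highest other split called 55. This is the smallest share that 100 splits can give, so chance is unlikely but not excluded. The real split was also the 1 of 100 as large for SRF with 7371 genes and 2457 in the highest other, NFYA with 6021 and 4272, and PRPF4B with 5611 and 3687. These 3 were chosen for having the most called genes, and the count of splits does not allow for that choice, nor for the 3 guides of SRF lying in 1 block of library numbers. For LATS2 3 of 100 splits called at least 17 genes, under 5 in 100, but 1 other split called 215, which points to a structure of the samples, so the number of called genes does not set LATS2 apart from other groupings. For CSK the real split called 0 genes in edgeR, a number that each of the 100 splits reaches, so the splits say nothing about chance; the highest other called 4, DESeq2 called 76 in the real split, and 1361 genes had an unadjusted p under 0.05 in edgeR.

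WT and neg were 1 gene apart in a fit of these controls alone, and 6 of 100 splits called as many, so chance cannot be excluded. The highest other split called 801 genes, which points to a structure of the samples. The block of library numbers fits this, as 5080 of 12790 genes were called between the 10 controls of the first block and the 19 of later blocks, 2469 higher in the first block and 2611 lower. What differed between the blocks, such as the day of culture or the sequencing run, is not in the labels, and no biological explanation was tested.

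SRF, NFYA and PRPF4B shared a broad change, and guides of 12 other targets lay with theirs at the far end of the first principal component, 13 of these 22 libraries in the first block of library numbers, 6 in the second and 3 in the last. The tables argue against 3 explanations for the whole of it: at least 79.4% of the called genes stayed called with the same sign after a trend with gene length and GC content was removed from each library, at least 92.4% with the block as a covariate, and at least 69.0% without libraries under 2000000 counts. Fewer dividing cells were taken to lower the mitosis list, whose lowest median log2 fold change in the 3 knockouts was 0.99. These mRNAs were thus not lower, but they do not show how often cells divided, so this test cannot decide on fewer dividing cells. Libraries under 2000000 counts made up 36.4% of the 22 libraries and 13.1% of the other knockout libraries. The 50 most abundant genes took a median of 10.5% of counts in the 22 libraries and 12.6% in the other knockout libraries, and lower RNA quality of single libraries cannot be told apart from a change in expression, because the table holds no measure of quality apart from expression. In NFYA and PRPF4B guide 3 had 28 and 23 called genes when it stood alone, so an effect of single guides or of the state of single cultures may contribute, and neither was tested.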
